A study of Homo sapiens with 12 samples.

How the data were processed

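Whole transcriptomes were measured in 12 libraries of LPS-stimulated THP-1 macrophages, 6 with the miR-122-5p mimic and 6 with a control mimic. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 µg of it with an NEBNext Ultra RNA kit. The sequence of the control mimic and the strand setting of the counting are not given in the sources used here. The authors deposited one table of raw read counts per gene, with no normalization. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the hg38 build, without saying how each was set. All 58735 gene identifiers in the table were found in GENCODE 29, which was used for symbols, coordinates, transcript GC content, transcript length and 3′ UTRs. Transcript GC content and length were those of each gene's longest annotated transcript, which need not be the one expressed. Columns were assigned to groups from their names and the sample titles; columns named for the miR-122-5p group matched its titles, and the control columns were taken as the control mimic group by their names and numbers. Reads counted without strand would mix overlapping antisense genes, and reads with several equally good positions are usually not counted, so near-identical copies and overlapping genes are uncertain.

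Library totals ran from 29473750 to 39468157 counts. In R 4.3.3, genes with low counts were removed with filterByExpr (15471 kept; 28537 had 0 counts in all libraries), TMM factors were computed, and the groups were compared with edgeR 4.0.16 by its quasi-likelihood test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are miR-122-5p over control mimic with their standard errors, and CPM values are scaled by TMM factors; log2 CPM used a prior count of 2. The median standard error was 0.124. In simulated counts for the 15471 genes with planted changes, edgeR recovered 4% of genes planted at a log2 change of 0.25, 57.1% at 0.5, 77.6% at 1 and 95.9% at 2, with 6 false calls, and made 0 calls with nothing planted. Changes were planted in a small share of the genes, far fewer than were called in the data, so these shares do not carry over to the data. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 7.84 to 73.0), so none was a second copy of another; this does not show that they came from separate cultures.

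Gene lists were fixed before the data were examined: 49 lists of interferon, inflammatory, antigen presentation, metabolic, stress, proliferation, cell type and microRNA target genes, written from general knowledge. Those with at least 5 tested members (46) were tested with limma 3.58.1 by camera at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, adjusted over the lists. The test was checked on simulated data, where the planted list was called and 0 others. The simulated genes varied independently of each other, so this check does not bear on the preset correlation. Named genes followed a rule also fixed then: the 8 largest changes in each direction among called genes with a mean log2 CPM of at least 3 and no overlap between groups, the 4 smallest p in each direction, 8 known miR-122 targets, up to 4 members of smallest p in each list described, and 7 LPS readouts. Other genes are named only as chosen after their values were seen. The value of 1 such gene is not reported here.

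For target sites, the longest annotated 3′ UTR of each gene was searched for matches to the seed of miR-122-5p (whole sequence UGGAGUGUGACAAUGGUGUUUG), each gene placed in its strongest class: 8mer, 7mer-m8, 7mer-A1, 6mer or none. The mean log2 CPM of a class minus that of genes with no site was compared between groups by a two-sided exact permutation test over libraries; the same was done for 7-base words, ranked by the adjusted difference divided by its standard error and, added after the data were seen, by the difference itself. A planted shift of -0.2 was recovered as -0.207 in a check on simulated data. That shift was larger than the differences found, and it was planted in values from which the group differences had been removed. The check therefore does not show that differences of the size found can be told from a GC trend. Library measures were compared by the same exact test.

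The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE size factors, library totals without composition scaling, no low-count filter, a filter at 1 CPM in 6 libraries, the replicate number as a block, each library left out in turn, a minimum fold change, an adjusted p under 0.01, no mitochondrially encoded genes, the camera and fry variants, and other definitions of the UTR and its adjustment. Added after seeing the data were a correction of each library's trends with transcript GC content and length (natural splines with 4 degrees of freedom, as offsets), each library's GC slope as a covariate, a fit without control libraries 1 and 6, sample quality weights in limma-voom, site matches inside an Alu motif left out, and site tests without interferon-list genes. Results that pass the threshold in neither setting were counted as unmoved. Outlying libraries were sought by Dixon's ratio within groups of 6. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for site tests, tables and figures.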

Results

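RNA was sequenced from THP-1 macrophages, cells of a human monocytic leukaemia line with a macrophage phenotype, that had received a synthetic mimic of the microRNA miR-122-5p or a control microRNA mimic. The mimics were used at 30 nM for 24 h, and the cells were then rested and stimulated for 4 h with lipopolysaccharide (LPS), the bacterial cell wall component sensed by TLR4. The labels give the purpose as the immunoregulatory action of exosomal miR-122-5p. There were 6 libraries in each group. The labels do not say whether the 6 came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries of the miR-122-5p group held 29473750 to 35684464 gene counts and control libraries 31019890 to 39468157. The totals did not differ detectably (33494000 ± 2555000 against 34669000 ± 3057000, SD, n = 6 in each group, two-sided exact permutation p = 0.504).

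The first comparison asked which genes differed between miR-122-5p and control mimic after LPS. The genes with the largest falls in the miR-122-5p group were those of interferon and its target genes. IFNB1, which encodes interferon beta, averaged 7.68 ± 1.25 CPM (normalised count relative to library size; SD, n = 6) with miR-122-5p and 115.1 ± 17.6 with the control mimic (log2 fold change -3.90 ± 0.12, SE; adjusted p = 4.41e-16). IFNL1, a type III interferon, changed by -3.70 ± 0.15. The monocyte-attracting chemokines CCL8, CCL7 and CCL2 changed by -5.41 ± 0.35, -4.29 ± 0.19 and -3.74 ± 0.20, the tryptophan-degrading enzyme IDO1 by -5.35 ± 0.27, SECTM1 by -4.64 ± 0.14 and the chemokine CXCL11 by -3.69 ± 0.21. CCL8 averaged 20.9 ± 14.4 CPM against 888.2 ± 202.4, and IDO1 8.42 ± 4.74 against 343.7 ± 79.0 (n = 6 in each group).

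**Figure D1:**
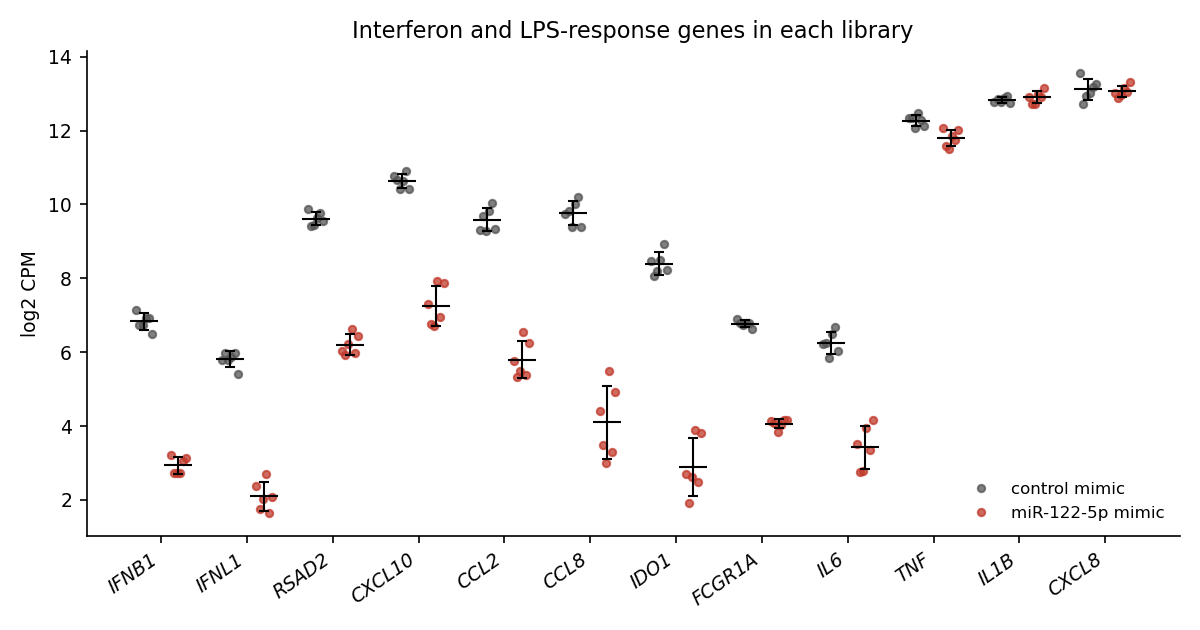
Log2 CPM (vertical axis) of 12 interferon and LPS-response genes (horizontal axis) in each of the 6 control mimic libraries (grey) and 6 miR-122-5p libraries (red), with the mean and SD as black bars. IFNB1, IFNL1, RSAD2, CXCL10, CCL2, CCL8, IDO1, FCGR1A and IL6 lay lower in every miR-122-5p library than in any control library, while IL1B and CXCL8 overlapped.

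The genes with the smallest p among those that fell were FCGR1A, a high-affinity receptor for IgG (-2.71 ± 0.08, adjusted p = 3.02e-16), ENDOD1 (-2.88 ± 0.09), SECTM1 and IFNB1. Reads of FCGR1A can be shared with near-identical copies, so its value is uncertain. CCL8 lies on chromosome 17 (34319036 to 34321402), IDO1 on chromosome 8 (39902275 to 39928444), SECTM1 on chromosome 17 (82321024 to 82334074), IFNB1 on chromosome 9 (21077105 to 21077963) and FCGR1A on chromosome 1 (149782671 to 149792518), in the hg38 build. Each is annotated as a protein-coding gene.

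Increases were smaller. PLAT, tissue plasminogen activator (chromosome 8, 42175233 to 42207724), rose by 2.58 ± 0.16 on the log2 scale, from 3.55 ± 0.638 to 21.2 ± 4.86 CPM (n = 6, adjusted p = 2.20e-11). The adrenergic receptor gene ADRA2B (chromosome 2, 96112875 to 96116245) rose by 1.82 ± 0.10, NT5DC2 by 1.77 ± 0.15, IQGAP3, a scaffold protein linked to proliferation, by 1.69 ± 0.15, the collagen gene COL11A2 by 1.45 ± 0.09 and the chemokine CCL22 by 1.42 ± 0.08. RN7SL2, a 7SL RNA with near-identical copies, rose by 2.18 ± 0.27, TAF10 by 2.14 ± 0.22, and the processed pseudogenes RPL3P4 and PPP1R14BP3 by 1.74 ± 0.16 and 1.73 ± 0.21. These 4 are uncertain, because their reads can be shared with near-identical genes or, for TAF10, with genes overlapping 51.2% of its exons. The GC slope covariate described with the GC trend ended the calls of RN7SL2 (adjusted p = 0.0745) and PPP1R14BP3 (0.140), and the GC and length correction left PPP1R14BP3 at 1.13.

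Of 15471 genes tested, 7810 (50.5%) changed at an adjusted p under 0.05, 3756 higher and 4054 lower in the miR-122-5p group. At least 2-fold changes were found for 586 higher and 859 lower genes, and at least 8-fold changes for 2 higher and 69 lower. The 6 values of one group did not overlap the 6 of the other for 4557 genes (29.5%), where chance gives 0.216%. Fold changes followed transcript GC content: the median log2 fold change was -0.296 in the 3093 genes of lowest GC content (26.8 to 41.3%) and 0.388 in the 3093 of highest (58.4 to 84.3%). With each library's GC slope as a covariate, 2806 genes were called, 1015 higher and 1791 lower (36.2% higher, against 48.1% without the covariate); this setting was added after the data were seen.

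**Figure D2:**
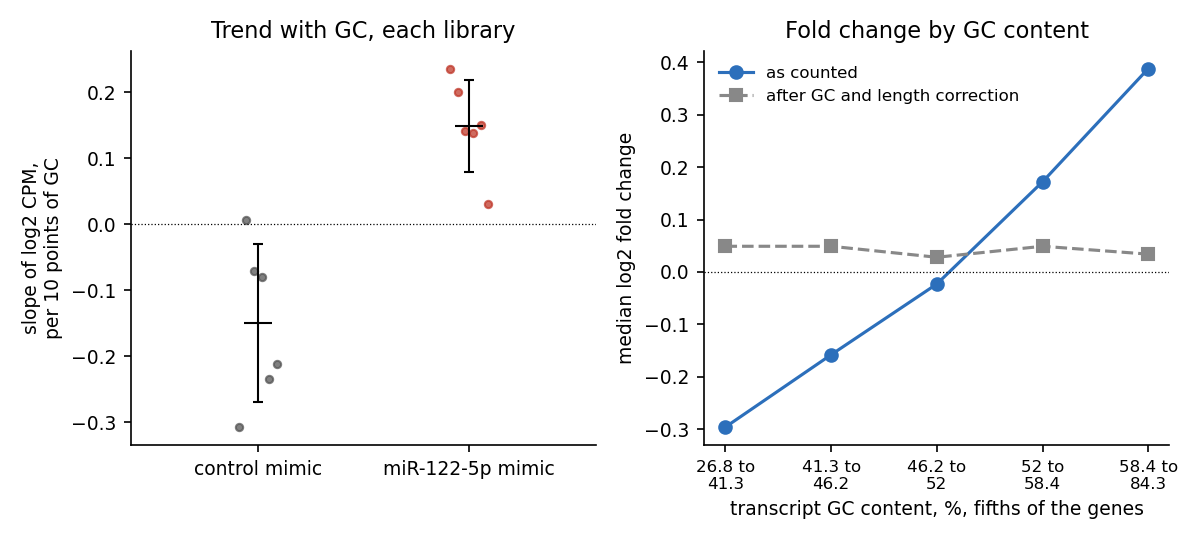
Left, slope of log2 CPM on transcript GC content (per 10 percentage points, vertical axis) in each library of the control mimic and miR-122-5p groups, with mean and SD in black; the slopes ran from -0.307 to 0.006 and from 0.030 to 0.236. Right, median log2 fold change (vertical axis) of genes grouped by transcript GC content (horizontal axis), as counted and after the GC and length correction, rising from -0.296 to 0.388 as counted.

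The libraries also differed in this respect one by one. The slope on transcript GC content of each library's log2 CPM, taken relative to the mean over libraries, was examined after the data were seen. Per 10 percentage points it averaged 0.149 ± 0.070 (SD, n = 6) with miR-122-5p and -0.149 ± 0.119 with the control mimic, without overlap (two-sided exact permutation p = 0.00217, the smallest that 6 against 6 can give). More genes were detected with miR-122-5p (21257 ± 187 against 20656 ± 726, n = 6; exact permutation p = 0.0368, 0.147 after Benjamini-Hochberg adjustment over 4 measures), which failed the correction. The unadjusted exact p ended above 0.05 without any single miR-122-5p library (0.0541 to 0.0996) and without control library 6, where the excess was 329.8 genes (0.0779). The share of counts in mitochondrially encoded genes (2.92 ± 0.237% against 3.04 ± 0.379%, exact permutation p = 0.522) and in the 20 most abundant genes (16.7 ± 0.480% against 16.5 ± 0.227%, exact permutation p = 0.416) did not differ detectably at n = 6. Control libraries 1 and 6 stood apart on the third and second principal components.

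The second comparison asked which gene groups moved. The 44 tested type I interferon-stimulated genes, the antiviral programme induced by interferon alpha and beta, fell together: 43 were lower, 0 higher and 1 not called, with a median log2 fold change of -1.36 (camera adjusted p = 2.03e-25; adjusted p = 0.0926 with an estimated correlation). Examples were RSAD2, an antiviral enzyme (-3.40 ± 0.12), TRIM22 (-2.34 ± 0.09) and MX2 (-1.60 ± 0.07). Of 28 interferon-gamma response genes, 22 were lower, 1 higher and 5 not called (median -1.69, adjusted p = 1.06e-12; adjusted p = 0.123 with an estimated correlation), among them the tryptophanyl-tRNA synthetase WARS1 (-2.37 ± 0.07), APOL1 (-2.36 ± 0.08) and the guanylate-binding protein GBP3 (-2.16 ± 0.09). After the GC and length correction the medians of these lists were -1.29 and -1.62, and the median of all tested genes was 0.01 before it.

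Antigen presentation genes fell as well, but in part these are the same genes. TAP1, TAP2, PSMB8 and PSMB9 of the class I list and CIITA of the class II list are also in the interferon-gamma list. In MHC class I presentation 15 of 17 genes were lower and 0 higher (median -0.49, adjusted p = 4.20e-06), including the peptide transporter subunits TAP1 (-1.27 ± 0.07) and TAP2 (-1.17 ± 0.07) and the immunoproteasome subunit PSMB9 (-1.25 ± 0.09). In MHC class II presentation 9 of 13 were lower and 1 higher (median -0.72, adjusted p = 0.000224), including HLA-DRA (-2.03 ± 0.09) and the class II transactivator CIITA (-2.40 ± 0.19). CIITA had low counts (0.859 ± 0.134 against 4.56 ± 0.913 CPM, SD). Other genes overlap 23.4% of the exons of CIITA and 32.3% of those of TAP2, so both values are less certain. Inflammasome and pyroptosis genes were lower for 11 of 17 and higher for 0 (median -0.66, adjusted p = 0.000134), with CASP1 at -2.24 ± 0.08, the DNA sensor AIM2 at -1.81 ± 0.11 and CASP4 at -1.42 ± 0.09. For each of these 3 lists the adjusted p was 0.0926 with an estimated correlation, and after the GC and length correction the medians were -0.63, -0.73 and -0.54.

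Chemokines went both ways, with 11 of 21 lower and 4 higher (median -0.40, adjusted p = 0.0106; adjusted p = 0.385 with an estimated correlation); CXCL10 fell by 3.31 ± 0.18, while CCL22 rose. TLR4 signalling genes were lower for 15 of 24 and higher for 2 (median -0.33, adjusted p = 0.0106; adjusted p = 0.160 with an estimated correlation). They included the adaptor MYD88 (-1.10 ± 0.07), IRAK4 (-1.27 ± 0.13), the co-receptor LY96 (-0.76 ± 0.09) and TLR4 itself (-0.85 ± 0.11; its call ended with the GC slope covariate, adjusted p = 0.0557). Cytokine signalling suppressors and kinases were lower for 11 of 20 and higher for 4 (median -0.31, adjusted p = 0.0454; adjusted p = 0.311 with an estimated correlation), with the kinase JAK2 at -2.26 ± 0.13, the interferon feedback gene USP18 at -1.30 ± 0.08 and STAT3 at -0.87 ± 0.06. JAK2 and STAT3 are known to transmit cytokine signals. The medians of these 3 lists after the GC and length correction were -0.32, -0.24 and -0.25, with LY96 at -0.49 and TLR4 at -0.52. The GC slope covariate ended the calls of the chemokine (adjusted p = 0.103) and TLR4 signalling lists (adjusted p = 0.0567); over all settings their adjusted p ran from 5.02e-06 to 0.385 and from 1.04e-06 to 0.160. Both low ends came from fry, which does not compare a list with other genes. The suppressor call ended under the stricter low-count filter (adjusted p = 0.0874) and without miR-122-5p library 2 (0.0604) or control library 2 (0.0659), within a range of 1.24e-06 (with fry) to 0.311.

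The lists that rose numbered 5. DNA replication genes were higher for 21 of 23 and lower for 1 (median 1.08, adjusted p = 3.33e-08), with the cell cycle transcription factor E2F1 at 2.02 ± 0.16 and the helicase subunits MCM7 and MCM4 at 1.12 ± 0.10 and 1.08 ± 0.11. Mitosis genes were higher for 17 of 21 and lower for 0 (median 1.05, adjusted p = 4.29e-07), with BIRC5 at 1.68 ± 0.18 and CDK1 at 1.22 ± 0.13. Several of these had low counts, such as E2F1 with 11.8 ± 1.66 against 2.90 ± 0.797 CPM (n = 6). Cholesterol synthesis genes were higher for 16 of 24 and lower for 1 (median 0.28, adjusted p = 0.000376), including MVD (1.04 ± 0.08) and DHCR7 (1.12 ± 0.10). For these 3 lists the adjusted p was 0.0926 with an estimated correlation, and the medians after the GC and length correction were 1.08, 1.30 and 0.36, with MVD smaller at 0.66.

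Ribosomal protein genes were higher for 29 of 30 and lower for 1 (median 0.45, adjusted p = 9.97e-10; adjusted p = 0.160 with an estimated correlation), with RPL8 at 1.16 ± 0.10 and RPS3 at 0.76 ± 0.07. Oxidative phosphorylation genes were higher for 16 of 29 and lower for 1 (median 0.29, adjusted p = 0.000199; adjusted p = 0.385 with an estimated correlation), with the cytochrome c oxidase subunit COX5B at 0.85 ± 0.08 and the cytochrome CYC1 at 0.67 ± 0.08. After removal of the GC and length trends the medians of these 2 lists were 0.50 and 0.35, but RPL8 was at 0.69 and CYC1 at 0.21 (adjusted p = 0.0119). In all, 13 of 46 lists passed with the preset correlation of 0.01 and 0 with an estimated one. Some lists share genes, such as CXCL10 and JAK2 with the interferon-gamma list, so the 13 are not separate findings. The rotation test fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, called 31.

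**Figure D3:**
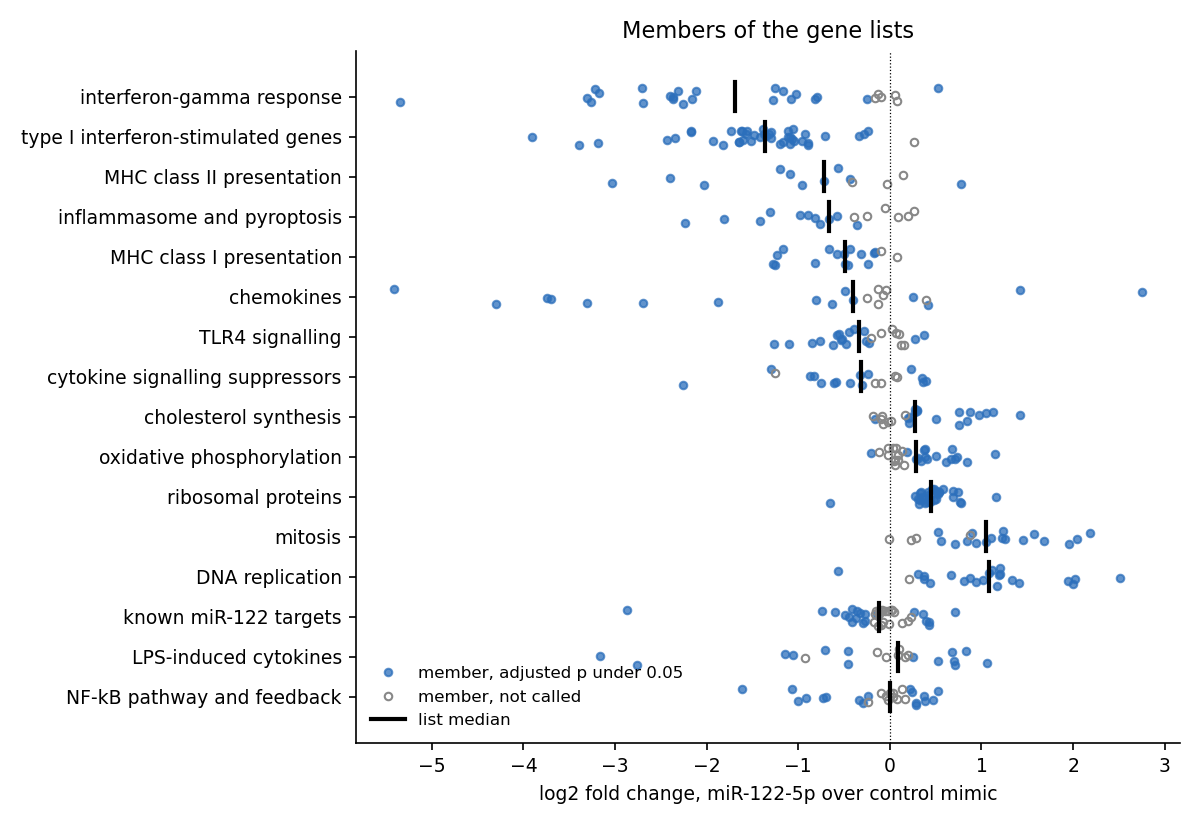
Log2 fold change of miR-122-5p over control mimic (horizontal axis) for each tested member (points; filled, adjusted p under 0.05; open, not called) of the 13 lists past the threshold and 3 further lists (vertical axis), with list medians as black lines. Medians ran from -1.69 for the interferon-gamma response to 1.08 for DNA replication, and those of LPS-induced cytokines (0.08) and NF-kB pathway genes (0.00) lay near 0.

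Adjusted over the list alone, the counts were the same for 9 of these 13 lists; they were 43 lower and 1 higher for type I interferon-stimulated genes, 15 lower and 3 higher for TLR4 signalling, 12 lower and 4 higher for cytokine signalling suppressors, and 17 higher and 2 lower for cholesterol synthesis.

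The classical LPS response did not move as one group. TNF fell by 0.46 ± 0.09 (3605 ± 564 against 4966 ± 524 CPM, n = 6), IL6 by 2.77 ± 0.20 and IL10 by 0.46 ± 0.12, whereas IL1B (0.08 ± 0.07, adjusted p = 0.343) and CXCL8 (-0.07 ± 0.10, adjusted p = 0.603) were not called. After the GC and length correction IL1B was called higher (0.20, adjusted p = 0.0102), as was CXCL8 (0.34, adjusted p = 0.000104), which also turned its direction with the GC slope covariate (0.61). The covariate ended the calls of TNF (-0.46, adjusted p = 0.0575) and IL10 (-0.08, adjusted p = 0.851). The fall of TNF was as large as before, while that of IL10 shrank. Over all settings the adjusted p of TNF and IL10 ran from 5.25e-06 and 0.000353 up to 0.0575 and 0.851. Among 21 LPS-induced cytokines 7 were higher, 7 lower and 7 not called (7 and 8 adjusted over the list alone; median 0.08, mean -0.27, adjusted p = 0.996); the falls included IL27 (-3.17 ± 0.18) and the activin subunit INHBA (-1.14 ± 0.08), and the rises LIF (0.83 ± 0.07). Of 27 NF-kB pathway genes 8 were higher, 9 lower and 10 not called (8 and 10 adjusted over the list alone; adjusted p = 0.708), with CD40 at -1.06 ± 0.09, the deubiquitinase CYLD at -0.91 ± 0.08, TNIP3 at -1.61 ± 0.17 and the survival gene BCL2A1 at -0.70 ± 0.08. After the GC and length correction this list passed (median -0.17, adjusted p = 0.0159), and CYLD was at -0.60.

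The third comparison asked whether transcripts that miR-122-5p could bind were lower. Genes with a site in the longest annotated 3′ UTR were slightly lower in the miR-122-5p group than the 8189 genes with no site. The difference in mean log2 CPM, miR-122-5p minus control, was -0.066 for 410 genes with an 8mer (ACACTCCA), -0.082 for 718 with a 7mer-m8 and -0.055 for 1901 with a 7mer-A1. It was 0.076 for the 1661 genes with only a 6mer. Each two-sided exact permutation p over the 6 and 6 libraries was 0.00217, the smallest they can give, and 0.00217 after adjustment over the 4 classes. This p asks whether the groups differ in the mean of a gene class, not whether the site is the cause. The 6mer class reached it with the opposite sign. Adjusted for UTR length, UTR GC content and expression, the differences were -0.035, -0.076, -0.017 and 0.022, with a smaller fall for the 8mer than for the 7mer-m8. Neither these tests nor those of 7-base words were repeated after the correction for transcript GC content and length. A part from that trend is therefore not excluded. Of genes with an 8mer 130 were lower and 90 higher, against 2332 lower and 2227 higher of those with no site. Without matches inside an Alu repeat motif, a choice made after the data were seen, the 7mer-A1 difference was -0.0295 (adjusted exact p = 0.0519).

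**Figure D4:**
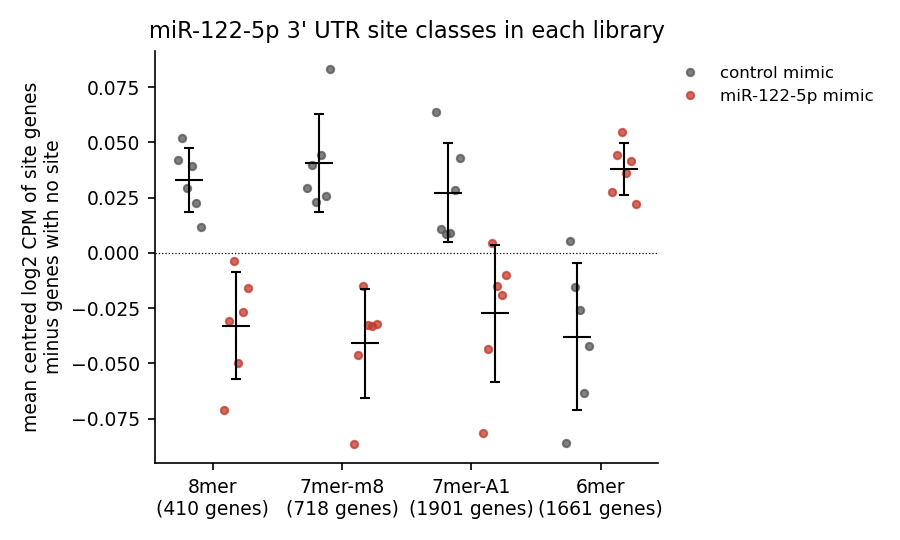
Mean log2 CPM, centred per gene, of genes with a miR-122-5p site minus genes with no site (vertical axis), for 4 site classes (horizontal axis), in each control mimic (grey) and miR-122-5p (red) library, with mean and SD in black. The mean differences were -0.066, -0.082, -0.055 and 0.076.

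Well-known miR-122 targets moved little. PKM, the glycolytic pyruvate kinase with an 8mer site (chromosome 15, 72199029 to 72231822), fell by 0.49 ± 0.06 (3098 ± 179 against 4339 ± 133 CPM, n = 6, adjusted p = 3.49e-07), and the glycogen synthase GYS1 by 0.27 ± 0.09 (adjusted p = 0.0120; -0.47 after the GC and length correction). The shedding proteases ADAM17 and ADAM10 fell by 0.35 ± 0.07 and 0.29 ± 0.07; both calls ended after the GC and length correction (-0.005, adjusted p = 0.951, and 0.05, adjusted p = 0.397), and their adjusted p over all settings reached down to 1.01e-05 and 0.000115. ALDOA, an aldolase whose exons overlap other genes over 53.5% of their length, fell by 0.60 ± 0.21 (adjusted p = 0.0207); its call ended with DESeq2 (adjusted p = 0.0787). The ALDOA call also ended without miR-122-5p library 2 (0.0506), control library 3 (0.0607) or control library 4 (0.0516), within a range over all settings of 1.30e-06 to 0.0787. The cyclin CCNG1 (-0.08 ± 0.08, adjusted p = 0.418) and the arginine transporter SLC7A1 (0.03 ± 0.08, adjusted p = 0.785), both with 8mer sites, were not called; CCNG1 was called higher after the GC and length correction (0.26, adjusted p = 0.00107). IGF1R held 99 counts over all libraries and was not tested.

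Across the 39 tested genes of the list of known miR-122 targets, 14 were lower, 6 higher and 19 not called, the same counts as adjusted over the list alone (median -0.12, adjusted p = 0.276). After the GC and length correction the list median was -0.01 (camera adjusted p = 0.179), again with 14 lower and 6 higher. With the GC slope covariate it was -0.13 (camera adjusted p = 0.103). NT5C3A (-2.87 ± 0.13), the chloride channel protein CLIC4 (-0.74 ± 0.09), PKM and the microtubule-binding protein MAPRE1 (-0.41 ± 0.07) had the smallest p. NT5C3A fell far more than the others. Like the interferon-stimulated gene RSAD2, it was highest in libraries 4 and 6 of the miR-122-5p group. Whether its fall belongs to that of the interferon genes was not tested. Of these 39 genes 23 (59.0%) held an 8mer or 7mer-m8 site, 9 of them among the 14 that were lower. The GC slope covariate ended the calls of CLIC4 (adjusted p = 0.0822) and MAPRE1 (0.215), the highest of any setting, and the GC and length correction left them at -0.34 and -0.20. The gene of miR-122 (MIR122) and its host transcript (MIR122HG) on chromosome 18 had 0 counts in every library; such libraries do not measure a transfected mature mimic.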

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

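The outlier tests were fixed before the data were examined; the tests of explanations in this part, except that on other groupings, were chosen after the results were seen. Chance flags about 1 in 20 groups, or 14.5 of the 290 groups of 6 values examined, and 15 values stood apart from the other 5 libraries of their group; 5 were in control library 1 and 4 in control library 6.

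In control library 1, log2 CPM of ALDOA was 2.07 (3.72 to 4.12 in the other control libraries), that of the respiratory chain gene NDUFA1 was 4.24 (4.70 to 4.97), the mean of the known miR-122 targets was 6.17 (6.26 to 6.30), that of mitochondrially encoded genes 9.02 (9.63 to 9.77), and the mitochondrial share of counts 2.30% (3.10 to 3.35%). In control library 6, log2 CPM of IFNL1 was 5.42 (5.79 to 5.99), the mean of inflammasome genes 6.21 (6.06 to 6.09), the 7mer-m8 site score 0.083 (0.023 to 0.044), and the number of genes detected 19298 (20545 to 21256). The mean of cholesterol synthesis genes was 5.86 in control library 4 (5.92 to 5.95). Control library 5 held the lowest means of fatty acid synthesis genes, 5.75 (5.84 to 5.88), and of cholesterol efflux genes, 6.64 (6.76 to 6.82). In miR-122-5p library 6, CTSL was at 10.78 (10.87 to 10.92) and the mean of matrix metalloproteinases and their inhibitors at 5.6 (5.74 to 5.80), and in miR-122-5p library 3 the genes detected numbered 21611 (21081 to 21263).

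The count of changed genes was higher for the real groups than for other groupings of these libraries. Of 100 splits of the 12 libraries into 6 and 6, drawn from 462, only the real one gave as many as 7810. The highest other split gave 3740. The splits treat libraries as separate units, which the labels do not state, so a difference between cultures by chance is not excluded.

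The first pattern is the fall of interferon genes with miR-122-5p. A GC or length bias would have to remove it, but after the correction the median of the type I list was still -1.29 and the list passed its test. Exchanged labels would make genes with the 7-base miR-122-5p match higher in the arm labelled miR-122-5p. These genes were lower by an adjusted -0.062, with 0.0862% of all 7-base words lower by the difference over its standard error and 1.08% by the difference itself. Only the first ranking meets the 1% bound set for this test. The adjustment was for UTR and not for transcript GC content. Whether the control mimic itself raised the interferon response cannot be told apart from an effect of miR-122-5p, since 0 of the 12 libraries had no mimic. An effect of miR-122-5p that lowers interferon output may be the cause, and stays open as untested.

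The second pattern is the rise of ribosomal protein and oxidative phosphorylation genes together with the GC trend between the groups. With GC and length trends removed the medians were 0.50 and 0.35, no smaller than before, so that trend, as measured on the longest annotated transcripts, is unlikely to be the whole cause. A bias with the GC content or length of the transcripts expressed is not excluded. Another scaling of the libraries moved the median of all genes by at most 0.0426, less than either list moved. The counts are relative, so a change in total RNA per cell is not seen, and a growth-related effect of the mimic may remain; it was not tested.

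The third pattern is the rise of DNA replication and mitosis genes. After the GC and length correction their medians were 1.08 and 1.30 (1.08 and 1.05 before). With the GC slope covariate the medians were 1.02 and 0.79, the second smaller than before, and both lists still passed. Without control libraries 1 and 6, which stand apart, the medians were 1.10 and 1.02, so those libraries do not set the difference. A larger share of dividing cells with miR-122-5p, or fewer with the control mimic, may explain the rise; counts from whole cultures do not separate a share of cells from a level per cell, and neither was tested.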

How the results depend on the processing

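The settings on GC content, without control libraries 1 and 6, with sample weights, without Alu matches and without interferon-list genes in the site tests were chosen after seeing the data; the others were fixed before. The count of changed genes stayed within 1.5 times of 7810 under DESeq2 (8085), limma-voom (7922), sample quality weights (8103), RLE factors (7807), library totals (7756), no filter (7921), the stricter filter (7497), an adjusted p under 0.01 (6030), no mitochondrial genes (7810), the GC and length correction (7324, 69.9% of the calls kept), without control libraries 1 and 6 (7489) and with each library left out (7235 to 7879). It moved to 1445 with a log2 change of at least 1 (586 higher, 859 lower), which only removes small changes, and to 2806 with the GC slope covariate (1015 higher, 1791 lower); the slope separates the groups completely, so this covariate also removes part of the group difference.

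The 13 list calls became 0 with an estimated correlation and 31 with fry, which asks a different question; with single libraries left out they numbered 12 to 14. ADAM10 (0.0541), CCNG1 (0.2643) and CXCL8 (0.3425) turned direction under the GC and length correction, and CXCL8 (0.6073) with the GC slope covariate. The covariate also ended the calls of 10 genes among the 89 named, not all of which were called without it. The cause was not tested. Of the named genes 89 kept their side of the threshold under RLE factors, library totals and the stricter filter, and 88 under DESeq2. There ALDOA lost its call with a similar fall (-0.59). The 7mer-A1 difference was -0.0295 without Alu matches. The excess of genes detected ran from 329.8 (without control library 6) to 721.4 with single libraries left out and was past the threshold in 5 of the 12 fits.

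Replicate numbers did not pair the libraries: correlations of same-numbered deviations ran from -0.105 to 0.066, and only number 2 had its own number as best partner. With the number as a block 7587 genes were called (95.4% of 7810 shared), and of the named genes only ALDOA crossed the threshold. In the simulated counts, 4% of genes planted at a log2 change of 0.25 and 57.1% at 0.5 were recovered. Far fewer genes changed there than in the data, which makes the threshold stricter, so the share missed in the data is not known.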

Other observations

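The tests of control mimic seeds and of the other hairpin arm were set before their results were seen, and the others, with the ranking of words by the difference itself, after. Genes named in this part were chosen after their values were seen. Several groups outside the 13 called lists held strong changes in both directions. Of 19 Fc receptor and phagocytosis genes 10 were lower and 5 higher (adjusted p = 0.0950), with the NADPH oxidase subunit CYBB at -1.65 ± 0.09 and the actin regulator CORO1A at 0.91 ± 0.11. Of 19 complement and coagulation genes 10 were lower and 4 higher (adjusted p = 0.0763), with C2 at -1.62 ± 0.11 and the receptor C3AR1 at -1.45 ± 0.10. Alternative activation markers were lower for 9 of 16 and higher for 3 (adjusted p = 0.292), with the lectin CLEC7A at -1.70 ± 0.15 and the scavenger receptor MSR1 at -2.29 ± 0.11. Fatty acid synthesis genes were higher for 10 of 19 and lower for 4 (adjusted p = 0.0861), with DGAT2 at 1.01 ± 0.08 and ACSL4 at -0.64 ± 0.09. The Fc receptor and complement lists passed after the GC and length correction (adjusted p = 0.00779 and 0.0259), as did NF-kB pathway genes (median -0.17, adjusted p = 0.0159); with the GC slope covariate the Fc receptor list (0.00282) and fatty acid synthesis genes (0.0326) passed. Over all settings the adjusted p of these 4 lists reached up to 0.466, 0.160, 0.957 and 0.161. Adjusted over the list alone, the counts given for the Fc receptor, complement, alternative activation, fatty acid synthesis, unfolded protein response, metallothionein, hypoxia and B cell lists were the same.

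Unfolded protein response genes were lower for 11 of 20 and higher for 2 (adjusted p = 0.0684), with the chaperone HSPA5 at -0.62 ± 0.07 and XBP1 at -0.60 ± 0.07; the list passed without control library 1 (0.0332) or control library 2 (0.0476), within a range over all settings of 2.58e-05 to 0.385. The low end came from fry, which does not compare the list with other genes. The list median of -0.33 became -0.11 after the GC and length correction (camera adjusted p = 0.0555). Of 8 metallothionein-list genes 5 were lower and 0 higher (adjusted p = 0.228), with MT2A at -1.07 ± 0.15. Hypoxia genes went both ways (6 higher, 3 lower of 19, adjusted p = 0.766), HIF1A at -0.999 ± 0.110 and DDIT4 at 1.01 ± 0.14. Among B cell markers, 2 of 5 were lower and 1 higher (adjusted p = 0.187): PAX5 and BANK1 changed by -3.36 ± 0.13 and -3.01 ± 0.27. Adjusted p was above the threshold for the lists not yet named: macrophage differentiation 0.708, cholesterol efflux 0.427, glycolysis 0.708, the TCA cycle 0.383, amino acid stress 0.996, amino acid transporters 0.370, p53 targets 0.708, oxidative stress 0.766, heat shock 0.427, autophagy and lysosome 0.708, MAPK and AP-1 feedback 0.930, ADAM proteases 0.708, integrins 0.708, matrix metalloproteinases 0.930, prostaglandin enzymes 0.708, TGF-beta signalling 0.708, apoptosis regulators 0.148, neutrophil granule genes 0.930, T and NK cell markers 0.708, mitochondrially encoded genes 0.708 and immediate early genes 0.930. The erythroid (3 genes), hepatocyte (3) and epithelial and stromal (4) markers had too few tested members, with 1, 1 and 2 higher and 0 lower. Median, mean and test direction differed in sign for LPS-induced cytokines, macrophage differentiation, the TCA cycle, amino acid stress, integrins, matrix metalloproteinases, neutrophil granule genes and immediate early genes.

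The fall of interferon genes may come from direct miR-122-5p sites in them. As the whole cause, that would need sites in most of them, a bound chosen after the results were seen. IFNB1 held no site and SECTM1 an 8mer. Without counting 7mer-A1 sites, 6 of 44 type I interferon genes (13.6%) held an 8mer or 7mer-m8, against 8.74% of other genes (Fisher's exact p = 0.276, 0.999 adjusted over 45 lists). Most members held no such site, so sites of these 2 classes in each gene's own longest 3′ UTR are not the whole cause. The count does not cover a site in a gene that acts upstream of the list, and that was not tested. Among the TLR4 signalling genes named above, TLR4 held a 7mer-m8 and IRAK4 a 7mer-A1, while MYD88 and LY96 held none. Small RNA machinery genes held an 8mer or 7mer-m8 in 30.0% (Fisher's exact p = 0.00590, 0.133 adjusted over 45 lists), which fails the correction. Of these 20 genes 10 were lower and 2 higher (13 and 3 adjusted over the list alone), with a camera adjusted p of 0.0763. The exonuclease XRN1 was at -1.89 ± 0.08 and DICER1 at -0.74 ± 0.12. The list median of -0.28 became 0.001 after the GC and length correction (camera adjusted p = 0.549), with 5 genes lower and 4 higher. The fall of the list therefore did not outlast the GC trend.

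The rise of genes with miR-122-5p could reflect targets of the control mimic in the other arm, whose sequence is not given. Genes with the 7-base match of 3 commonly used control seeds were examined. Divided by its standard error, the adjusted difference lay above 65.8% (cel-miR-67-3p), 51.1% (cel-miR-239b-5p) and 86.3% (a generic siRNA control) of all 7-base words, and undivided above 63.3%, 50.8% and 92.2%, inside the middle 90% set beforehand as the bound that counts against each. Genes with the generic siRNA match were nonetheless higher, by 0.048 adjusted and 0.079 unadjusted (two-sided exact permutation p = 0.00217, the smallest possible), so a small part from such a seed is not ruled out. A second microRNA from the other hairpin arm, miR-122-3p, could lower genes too, but genes with its match were slightly higher once adjusted for UTR length, UTR GC content and expression (0.028; -0.043 unadjusted), and 78.5% of all words lay lower (82.3% by the difference itself). The miR-122-5p match (ACACTCC) lay lower than all but 14 of 16243 words by the difference over its standard error, and than all but 176 by the difference itself. By the adjusted difference it was the lowest of 105 words of the same base composition, itself included; without the adjustment 12 of the 105, itself included, were as low or lower.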
